A study of Mus musculus with 9 samples.

How the data were processed

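Total RNA of normal colonic mucosa from 9 samples was measured on Agilent mouse arrays with 1 dye (Cy3). Each of 9 scanner files held 43379 spots of 41174 probes, and 1639 control spots, which were left out. Per the file headers, the values used (gProcessedSignal) are intensity after subtraction of background and spatial detrending within the array by Feature Extraction 10.5.1.1, with no scaling between arrays; the columns gMedianSignal and gBGMedianSignal are unprocessed median intensity of spot and local background. The deposited value table of the authors holds log2 values of 21829 probes. Set against the scanner files, each array's values were the log2 of gProcessedSignal minus 1 constant per array, with an SD of the difference of at most 0.0091; which quantity the constant is stays unknown. No spot was saturated.

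Spots marked by the scanner software as outliers were set to missing, and the spots of a probe were averaged. Values were log2 of gProcessedSignal minus the 75th percentile of the array. A probe with several spots counted as well above background on an array when any of them was. A probe was kept when well above background on at least 3 of the 9 arrays (28529 probes) and with at least 2 values per group (28521). RefSeq accessions gave 26933 probes 1 gene symbol. The 14241 others had no name, and the 6618 of them that passed the filters were kept as features. The DMH files carry another version of the probe annotation, in which 4725 probes have another accession, and 1 version was used for all arrays. Per gene the probe with the highest mean over all 9 arrays was used, which left 21964 features, 15346 of them named. No genome build was used, and no positions are given.

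Groups followed the titles, descriptions and source names of the samples: butyrate without tumors (3), butyrate with tumors (3) and DMH (3). The comparison of all 6 butyrate arrays with the 3 DMH arrays was fitted with 2 groups, and the other comparisons in 1 fit with 3 groups that shares 1 estimate of the spread. limma 3.58.1 (lmFit and eBayes, moderated test, 2-sided) in R 4.3.3 gave log2 fold changes, standard errors and p-values, adjusted by Benjamini and Hochberg over all features, with calls under 0.05. A fold is given as "at least" when a group was well above background on none of its arrays, against the lowest signal called well above background on each array.

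Of 43 gene lists of pathways and cell type markers, 42 had at least 5 measured members and were tested with camera at its preset correlation of 0.01, adjusted over the 42 lists of a comparison; erythrocyte genes had too few. Camera with an estimated correlation and fry (statmod 1.5.0 for the latter and for duplicateCorrelation) were run beside it. The lists, the comparisons, the alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. By that rule the text names, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among those whose groups do not overlap, up to 4 members of each called list by smallest p, called members of other lists, and fixed genes of butyrate handling, DMH handling, growth and mucus. Arntl, Npas2, Ms4a2, Tac1, Tnfaip3, Bub1, Sdha, Sdhb, Ceacam1, Lypd8 and Prox1, members that went against the call of their list, were chosen after their values were seen.

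Alternatives were quantile scaling, no scaling, normexp background correction (offset 50, then quantile scaling), the authors' values, other filters on dim probes and outlier spots, other ways to join the probes of a gene, a trend and robust prior, array weights, other thresholds, other groups in the fit, replicate number or slide as a block, and leaving out each array. Normexp used gMedianSignal, since the files have no column of mean spot signal. Chosen after seeing the data were slide as a random block, averages of DMH arrays and a fit without slide 1. The fit was tested on simulated data of 21964 features, with 100 changed by a log2 of 1 and 100 by a log2 of 2. At a log2 change of 2, with the spread of each group as measured, 72 were called for butyrate against DMH, 65 without tumors against DMH, 71 with tumors against DMH and 75 between the butyrate groups. At a log2 change of 1 these were 36, 34, 29 and 32. False calls among features left unchanged were 12, 17, 56 and 101, against 12, 4, 4 and 5 with 1 spread per gene in all groups. Between the butyrate groups the 101 false calls thus outnumbered the changed features called at each size taken alone (75 and 32), but not those of both sizes together. With only 100 features changed at each size, this share of false calls cannot be carried over to the real data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.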

Results

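Total RNA from the normal colonic mucosa of ICR mice, an outbred stock, was measured on 9 single-colour arrays of mouse genes. All mice received subcutaneous 1,2-dimethylhydrazine (DMH), a carcinogen that induces colon tumors in rodents, at 20 mg/kg a week for 20 weeks. The DMH group (3 arrays) had no other treatment. The other 6 arrays came from mice that also drank water with 1.5% butyrate, a short-chain fatty acid that fuels colonocytes and inhibits histone deacetylases, 3 from mice without tumors and 3 from mice with tumors. The tumor status is the one in the titles, descriptions and source names. A further label field gives the opposite status for all 6 butyrate samples, and if that field is right, every difference between the 2 butyrate groups turns its sign and the results of each against DMH belong to the other. The labels do not say whether the samples are separate animals, so the p-values measure only the spread between samples, and the number of arrays limits the precision.

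The signal at the 75th percentile of an array ran from 188 in array 1 with tumors to 880 in array 3 with tumors, and 57.8% to 72.5% of spots were well above background. The 3 arrays without tumors and array 1 with tumors lay on slide 1. Arrays 2 and 3 with tumors lay on slide 2. The DMH arrays lay on slides 3 and 4 and were scanned on another day than the butyrate arrays, so slide, scan day and treatment cannot be told apart in a comparison with DMH. On the first principal component, which held 47.0% of the variance, the 4 arrays of slide 1 lay between -99.2 and -54.1, arrays 2 and 3 with tumors at 38.1 and 44.6, and the DMH arrays at 57.3 and above. On the second component (21.1%) the arrays with tumors lay between -76.1 and -32.5, and all other arrays at 17.0 and above. The DMH arrays varied least, with a median SD per gene of 0.116 on the log2 scale, against 0.267 without tumors and 0.383 with tumors.

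**Figure D1:**
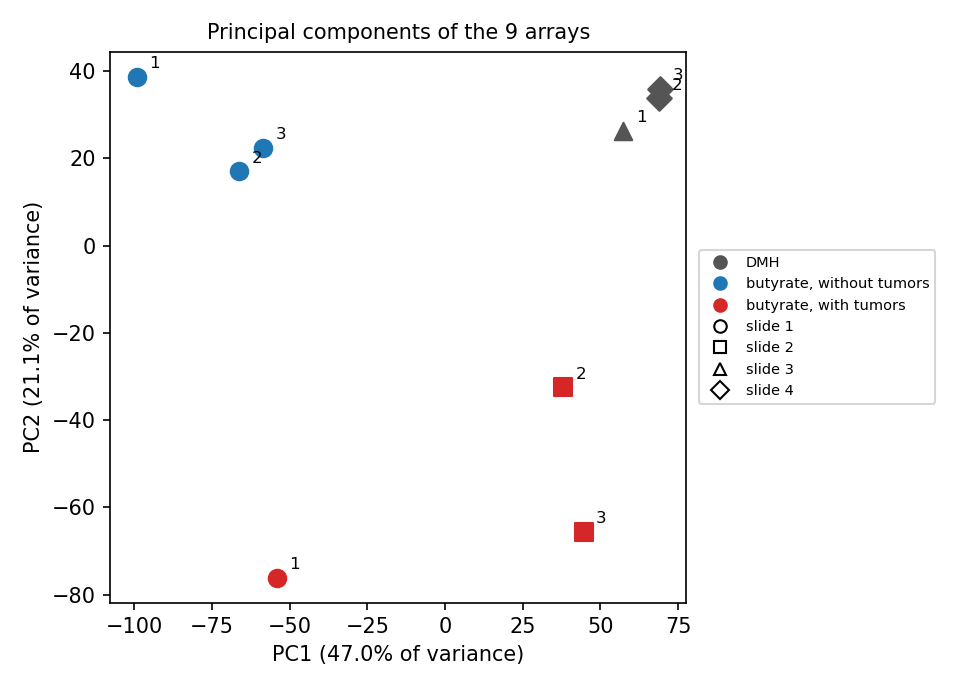
Principal components of log2 signal over 21855 features, 1 point per array, with colors for groups and symbols for slides. The arrays of slide 1 lie on the left of the first component (47.0% of the variance), and the 3 arrays with tumors lie lowest on the second (21.1%).

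All 6 butyrate arrays against the 3 DMH arrays is the comparison that the study's design text names. It asks which genes differ in DMH-treated mucosa with butyrate. Genes of goblet cells, which secrete the mucus layer, were lower with butyrate. Of 15 measured goblet cell genes 7 fell (10 adjusted over the list alone), and the list's median log2 change was -1.47 (camera, adjusted p = 8.83e-09, and adjusted p = 0.595 with an estimated correlation). Ang4, an antimicrobial protein of secretory cells, had a log2 change of -3.17 ± 0.22 (SE, 6 against 3 arrays, adjusted p = 0.000926). The trefoil peptide gene Tff3 (-2.12 ± 0.43, adjusted p = 0.0286) and the mucus protein gene Fcgbp (-2.06 ± 0.45, adjusted p = 0.0317) also fell, while the mucin gene Muc2 (-1.83 ± 0.51, adjusted p = 0.0522) did not pass. Genes of the muscle wall and its nerves were higher in the same arrays. Of 14 smooth muscle genes 3 rose (10 adjusted over the list alone; median 1.19, camera adjusted p = 0.000154), among them Pgm5, a protein of muscle adhesion sites, by 2.02 ± 0.39 (0.85, adjusted p = 0.0603, in a dimmer probe). Of 16 genes of enteric neurons and glia 5 rose (10 adjusted over the list alone; median 1.23, camera adjusted p = 0.000176), among them the neuropeptide gene Vip by 1.16 ± 0.26. Both lists had adjusted p = 0.595 with an estimated correlation. Relative to the DMH mean, the smooth muscle median of array 3 without tumors (0.367) lay below that of DMH array 1 (0.403).

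Clock genes moved in both directions. The transcription factors Dbp (1.92 ± 0.29, adjusted p = 0.017), Tef (2.10 ± 0.32), Hlf (2.19 ± 0.38) and Nr1d2 (1.41 ± 0.27), which carry or feed back the daily rhythm, rose, and Arntl (-1.07) and Npas2 (-1.33), which drive them, fell. The list of 17 was called higher (9 higher and 2 lower adjusted over the list alone; median 0.87, adjusted p = 0.0307). It missed the threshold with the authors' values (adjusted p = 0.053; 0.01 to 0.053 over 17 alternatives) and with an estimated correlation (adjusted p = 0.595 with an estimated correlation). Of 37 ribosomal protein genes 7 fell (16 adjusted over the list alone; median -0.62, adjusted p = 4.04e-09), for example Rplp0 by 1.95 ± 0.44 on the log2 scale, although a second bright probe of Rplp0 had -0.60 (adjusted p = 0.0855). Of 34 oxidative phosphorylation genes 6 fell (10 adjusted over the list alone; median -0.34, adjusted p = 7.70e-06), for example Cox6b1 (-1.47 ± 0.30), and of 21 genes of endoplasmic reticulum stress 6 fell (6 adjusted over the list alone; adjusted p = 0.0307), among them the chaperone gene Hspa5 (-0.89 ± 0.21). These 3 lists had adjusted p = 0.595 with an estimated correlation. Oxidative phosphorylation lost its call with quantile scaling (adjusted p = 0.0699; 3.64e-10 to 0.0699 over 17 alternatives), and endoplasmic reticulum stress lost it with quantile scaling (0.0714), with normexp background correction (0.0774) and without array 3 with tumors (0.121; 0.00236 to 0.121 over 17 alternatives).

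Markers of fat cells, neutrophils and mast cells were lower with butyrate as well. Adipocyte genes had a median of -1.82 over 10 members (adjusted p = 0.00562), although array 1 without tumors lay above the DMH mean (0.739) and the other 5 from -3.35 to -1.63. Neutrophil genes had a median of -2.52 over 7 (adjusted p = 0.00409), with the gelatinase gene Mmp9 falling by 2.88 ± 0.59, although array 3 with tumors lay above the DMH mean (0.299) and the other 5 from -4.08 to -1.08. Mast cell genes had a median of -1.48 over 9 (adjusted p = 0.027), although the 1 member that passed, the receptor subunit gene Ms4a2, rose by 1.98. Wnt target and crypt-base genes had a median of -0.50 over 21 (adjusted p = 0.000844), with the crypt receptor gene Ephb2 falling by 1.27 ± 0.33; the median was -0.75 without array 3 with tumors. With an estimated correlation each of these 4 had adjusted p = 0.595. Without the 4 arrays of slide 1, an alternative chosen after seeing the data, neutrophils (adjusted p = 0.313), mast cells (0.0688) and Wnt targets (0.342) were not called. Over their alternatives these 3 ranged from 0.0002 to 0.313, 0.0104 to 0.0688 and 4.49e-05 to 0.342. Further calls, all lower and each lost in at least 1 alternative, were xenobiotic metabolism (adjusted p = 0.027, and 2.68e-08 to 0.121 over 17 alternatives), p53 targets (0.0307, and 0.0161 to 0.22), DNA repair (0.027, and 0.0052 to 0.129), antimicrobial defence (0.0466, and 0.0298 to 0.369), tight junctions (0.0426, and 0.00236 to 0.131) and enteroendocrine cells (0.0496, and 0.00236 to 0.121). Members that passed were Aen (-1.03) and Pmaip1 (0.87) among p53 targets and Alkbh2 (-0.71) of DNA repair. Others were Itln1 (-2.94) and Ang4 among defence genes, Tjp3 (-0.94) of tight junctions, and Pcsk1 (-1.36) and Tac1 (0.99) among enteroendocrine genes. With an estimated correlation these 6 had adjusted p = 0.595 or 0.702. Without the arrays of slide 1, p53 targets (camera adjusted p = 0.22), DNA repair (0.129) and antimicrobial defence (0.369) were not called. Quantile scaling and normexp each ended the calls of xenobiotic metabolism, antimicrobial defence, tight junctions and enteroendocrine cells. Single arrays ended some of these calls as well. Without array 3 with tumors, xenobiotic metabolism had adjusted p = 0.121, tight junctions 0.101 and enteroendocrine cells 0.121. Without array 1 with tumors they had 0.0675, 0.131 and 0.0848. Without array 2 with tumors xenobiotic metabolism had 0.0541, enteroendocrine cells 0.0842 and antimicrobial defence 0.0743. DNA repair had 0.0622 without array 1 without tumors, antimicrobial defence 0.0716 without array 2 without tumors, antimicrobial defence and tight junctions 0.0528 without DMH array 2, and enteroendocrine cells 0.0673 without DMH array 1.

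Among single genes, Ccdc182 (at least 3.04-fold, adjusted p = 0.0079), the synaptic scaffold gene Dlg4 (at least 2.66-fold), the alcohol dehydrogenase gene Adh4 (log2 3.00 ± 0.61), Zfp979 (2.90 ± 0.60), the sodium channel gene Scn7a (at least 1.87-fold), and Sphkap (at least 1.75-fold) were among the 10 genes that rose most. So were the Wnt agonist gene Rspo2 (at least 2.56-fold), the choline transporter gene Slc5a7 (2.69 ± 0.45), Clvs2 (2.65 ± 0.71) and Klhl4 (at least 2.55-fold). Folds given as "at least" are against the lowest signal called well above background on each array, because the lower group was not well above it, and the order of genes follows the fitted values. Srrm3 (-5.67 ± 0.77), Mitf (at least 10.9-fold lower, adjusted p = 0.000122), Ang2 (-4.90 ± 1.06), Cacna1f (at least 5.85-fold lower), and Mmp13 (-4.22 ± 1.13) were among the 10 that fell most. So were the retinol receptor gene Stra6 (-4.03 ± 0.72), Mmp10 (-3.84 ± 1.03), Pinx1 (-3.49 ± 0.38, and -0.88 in a dimmer probe) and Trim55 (-3.41 ± 0.78). Of the 6 butyrate arrays 5 were well above background for Ang2, 3 for Mmp13 and Hcar2, and 1 for Trim55 and Cyp2e1, and of the 3 DMH arrays 1 was for Adh4 and Slc5a7. Mmp13 and Mmp10 encode enzymes that break down matrix. Ang2 and Ang4 belong to a gene family of closely similar sequence, in which a probe can read more than 1 member. Of the genes chosen beforehand for their role in butyrate or DMH handling, none passed. The butyrate transporter gene Slc5a8 had -0.48 ± 0.41 (adjusted p = 0.447), the fatty acid receptor gene Ffar2 -1.24 ± 0.43 (0.0914), and the butyrate receptor gene Hcar2 -2.02 ± 0.56 (0.0512). The cell cycle inhibitor gene Cdkn1a had -0.15 (0.727) and the DMH-activating enzyme gene Cyp2e1 -3.51 ± 1.02 (0.0594). Further values were Slc16a1 0.12 (0.717), Myc -0.47 (0.21) and Mki67 -0.48 (0.148).

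In limma, 2020 of 21964 features changed at an adjusted p under 0.05 (1285 higher and 735 lower; 1230 named genes), of 6857 with an unadjusted p under 0.05. The balance of directions depended on the scaling, with 857 higher and 895 lower after normexp and 469 higher and 728 lower in the authors' values. In 26.3% of features all 6 butyrate arrays lay on one side of all 3 DMH arrays, where chance gives 2.381%. Single arrays decided the count. It was 1289 without array 1, 263 without array 2 and 709 without array 3 without tumors, 3626 without array 3 with tumors, and 210, 7 and 8 without DMH arrays 1, 2 and 3. Of 72 called genes named by rule, 2 (Ang4 and Mitf) stayed called whichever array was left out. Over 175 probes with at least 8 spots on each array, the means of DMH arrays 2 and 3 differed by an SD of 0.0897. The scatter of duplicate spots alone would give 0.0422 for such means. DMH array 1, on another slide, differed from arrays 2 and 3 by 0.323 and 0.339. With DMH arrays 2 and 3 averaged into 1 sample 4 features were called (chosen after seeing the data). With all 3 DMH arrays averaged limma called 0 (1524 at an unadjusted p under 0.05). With slide as a random block, also chosen after seeing the data, 17 were called. The count was 35 with no scaling, 511 with no filter on dim probes, 12107 with array weights and 5051 in a fit with 3 groups.

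**Figure D2:**
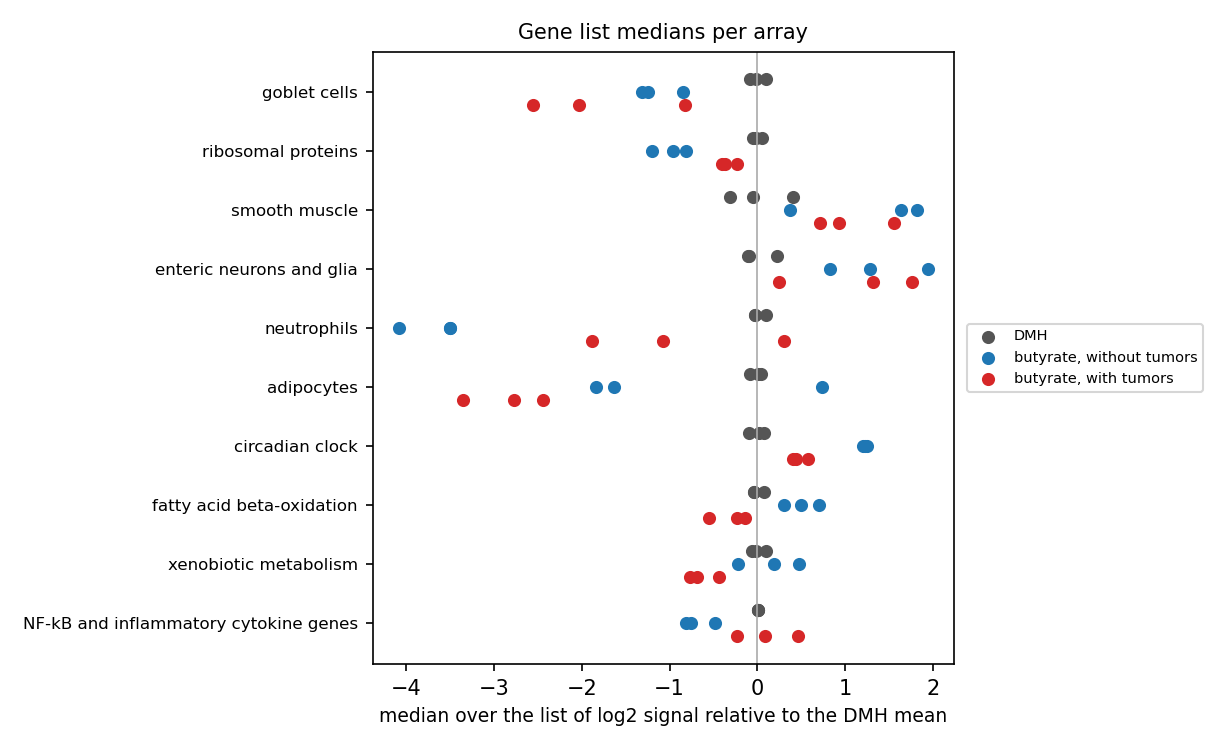
Median log2 signal of 10 gene lists relative to the DMH mean, 1 point per array, colored by group. All 6 butyrate arrays lie below 0 for goblet cells and above 0 for smooth muscle and enteric neurons, and the arrays without tumors lie lowest for neutrophils. For smooth muscle DMH array 1 (0.403) lies above array 3 without tumors (0.367).

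Butyrate arrays without tumors (3) against DMH (3) ask which genes differ between these 2 groups. The titles give no tumor status for the DMH group, so butyrate and tumor status cannot be told apart here. Inflammatory genes and markers of myeloid cells were lower without tumors. Of 7 neutrophil genes 6 fell (6 adjusted over the list alone; median -3.70, camera adjusted p = 0.000507, and adjusted p = 0.518 with an estimated correlation). The calprotectin subunit gene S100a8 was at least 15.1-fold lower, the lactoferrin gene Ltf at least 9.74-fold lower, and Mmp9 fell by 3.70 ± 0.44 on the log2 scale (SE, 3 against 3 arrays, adjusted p = 0.00178). With members not well above background at their bound the list median was -3.28. Of 33 genes of NF-kB and inflammatory cytokines 12 fell and Tnfaip3, a brake on NF-kB, rose (13 and 1 adjusted over the list alone; median -0.59, adjusted p = 0.00568, and adjusted p = 0.642 with an estimated correlation). The neutrophil chemokine gene Cxcl5 had -7.27 ± 0.90, with 1 of 3 arrays without tumors well above background, and the interleukin gene Il1b had -1.81 ± 0.34. This list missed the threshold in the authors' values (adjusted p = 0.0742; 0.00202 to 0.0742 over 16 alternatives). Of 15 genes of macrophages and dendritic cells 5 fell (adjusted p = 0.00568, and adjusted p = 0.464 with an estimated correlation), for example Fcgr1 (-2.58 ± 0.40), and of 9 mast cell genes 5 fell (adjusted p = 0.0117, and adjusted p = 0.642 with an estimated correlation), for example Fcer1a (-1.82 ± 0.24).

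Genes of the crypt base and of growth were called lower too. Relative to the DMH mean, medians of the Wnt list were -1.27, -1.14 and -0.918 in arrays 1 to 3 without tumors. Array 1 with tumors, also on slide 1, had -1.38, and arrays 2 and 3 with tumors had -0.265 and 0.386. The proliferation list had -0.607, -0.151 and 0.057 in arrays 1 to 3 without tumors. Of 21 Wnt target and crypt-base genes 10 fell (14 adjusted over the list alone; median -1.10, adjusted p = 0.000421, and adjusted p = 0.642 with an estimated correlation), among them the matrilysin gene Mmp7 (-4.98 ± 0.85), the transcription factor genes Lef1 (-1.42 ± 0.31), Tcf7 (-1.56 ± 0.37) and Sp5 (-3.91 ± 0.89), and Myc (-0.72 ± 0.21, adjusted p = 0.0339). Of 37 ribosomal protein genes 26 fell (27 adjusted over the list alone; median -1.07, adjusted p = 5.67e-15, and adjusted p = 0.106 with an estimated correlation), for example Rpl11 (-2.38 ± 0.14) and Rplp0 (-2.66 ± 0.22). The size of these falls depended on the probe, as second probes had -0.78 for Rplp0 (adjusted p = 0.0107) and, dimmer, -0.33 for Rpl23 (adjusted p = 0.167). A dimmer probe of Tcf7 had -0.35 (adjusted p = 0.574). Of 21 DNA repair genes 4 fell (adjusted p = 0.00494, and adjusted p = 0.769 with an estimated correlation), among them the alkylation repair genes Alkbh2 (-0.88) and Alkbh3 (-1.10), the latter with -0.08 in a second probe (adjusted p = 0.692). Of 38 proliferation genes 10 fell, such as Cdk1 (-1.24 ± 0.26), and 1, Bub1, rose. The list had a camera adjusted p = 0.0223, and adjusted p = 0.935 with an estimated correlation. Its call was lost without array 1 without tumors (adjusted p = 0.273) and without array 1 with tumors (0.0569; 0.000769 to 0.273 over 16 alternatives). A second probe of Bub1 had -0.38 in another comparison, that of all butyrate arrays with DMH. The Hcar2 gene, well above background on 1 of 3 arrays without tumors, fell by 2.75 ± 0.46, and of 10 histone deacetylase genes Hdac4 (-3.41 ± 0.56), Hdac2 (-0.95) and Hdac3 (-0.86) fell (adjusted p = 0.0461, and adjusted p = 0.464 with an estimated correlation). The histone deacetylase call was lost without array 1 (0.0697) or 3 (0.0645) without tumors, array 3 with tumors (0.0518) and DMH arrays 2 (0.069) or 3 (0.0583), and ranged from 0.0219 to 0.0697 over 16 alternatives.

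Goblet cell genes fell in 6 of 15 cases (8 adjusted over the list alone; median -1.21, adjusted p = 0.000507, and adjusted p = 0.642 with an estimated correlation), led by Ang4 (-3.35 ± 0.22, adjusted p = 0.000462), while Muc2 had -1.22 ± 0.45 (adjusted p = 0.0694). Smooth muscle genes rose in 8 of 14 cases (9 adjusted over the list alone; median 1.27, adjusted p = 0.00494) and enteric neuron and glia genes in 6 of 16 (7 adjusted over the list alone; median 1.35, adjusted p = 0.00741), both with adjusted p = 0.846 with an estimated correlation. Of 17 clock genes 8 rose and 2 fell (9 and 2 adjusted over the list alone; median 1.23, adjusted p = 0.00568, and adjusted p = 0.464 with an estimated correlation), such as Tef (2.55 ± 0.23), Cry2 (1.31) and the nuclear receptor gene Nr1d2 (1.80 ± 0.18). Of 23 genes of fatty acid beta-oxidation 9 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 0.0277, and adjusted p = 0.846 with an estimated correlation), with Hadha up by 1.36 ± 0.30. Its median was 0.53 but -0.55 with no scaling, where the median of all genes shifted to -1.004, and the call was lost in the authors' values (adjusted p = 0.0918), without array 1 without tumors (0.0567) and without array 1 with tumors (0.0552; 0.00719 to 0.0918 over 16 alternatives). Of 34 oxidative phosphorylation genes 12 fell and Sdha (0.61) and Sdhb (0.67) rose, by less than that shift (adjusted p = 0.0117, and adjusted p = 0.846 with an estimated correlation), a call lost with quantile scaling (0.585; 0.0044 to 0.844 over 16 alternatives). Antimicrobial defence genes fell in 4 of 15 cases (adjusted p = 0.0277, and adjusted p = 0.464 with an estimated correlation), including the lipocalin gene Lcn2 (at least 23.8-fold lower), with the call lost without array 2 without tumors (0.0627) and array 1 with tumors (0.0552; 0.0146 to 0.0627 over 16 alternatives). Genes of squamous epithelium fell in 5 of 10 cases (adjusted p = 0.0192, and adjusted p = 0.575 with an estimated correlation), a call lost in the authors' values (0.133; 0.00874 to 0.133 over 16 alternatives), led by Ly6d (-3.16 ± 0.35).

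Single genes that rose most without tumors included Scn7a (at least 2.68-fold), Rspo2 (at least 3.48-fold), Dlg4 (at least 2.94-fold), the glutamate receptor gene Gria1 (at least 4.02-fold) and Slc5a7 (log2 3.05 ± 0.48). Olfr1156 (3.72 ± 0.57), Sphkap, Ccdc182, Clvs2 and Klhl4 complete the 10. Largest falls were in Defa23 (-7.75 ± 1.21, with 1 of 3 arrays without tumors well above background), Cxcl5, Srrm3 (-6.87 ± 0.44), Ang2 (-6.38 ± 0.79), Defa22 (at least 18.1-fold lower), Defa20 (-6.23 ± 1.11), Mitf (at least 11.8-fold lower), Lcn2, Arid3a (at least 9.12-fold lower) and Mmp13 (-5.18 ± 1.21). Without tumors 2 of 3 arrays were well above background for Ang2 and 1 of 3 for Mmp13 and Cyp2e1, as was 1 of 3 DMH arrays for Slc5a7. The Defa genes encode defensins and the Olfr genes olfactory receptors, families of similar sequence in which a probe can read several members. Values that did not pass were Slc5a8 0.02 (adjusted p = 0.966), Ffar2 -0.63 (0.152), Cdkn1a 0.22 (0.371), Slc16a1 0.38 (0.092), Mki67 -0.58 (0.077) and Cyp2e1 -2.64 (0.0996).

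limma called 6695 features (3657 higher and 3038 lower; 4422 named genes) of 9778 with an unadjusted p under 0.05. With no scaling, which shifted the median of all genes to -1.004, 5 were higher and 1545 lower. In 60.0% of features the arrays of the 2 groups did not overlap, where chance gives 10%. The count was 3980 without array 2 without tumors, and 4158, 2841 and 2914 without DMH arrays 1, 2 and 3. It was 1010 with slide as a random block, 2909 with DMH arrays 2 and 3 averaged, 1550 with no scaling and 12768 with array weights, and 0 in limma with all DMH arrays averaged (4278 at an unadjusted p under 0.05). Of 171 called genes named by rule, 79 stayed called whichever array was left out.

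Butyrate arrays with tumors (3) against DMH (3) ask the same for butyrate mice that had tumors, again with no tumor status in the titles of the DMH group. Epithelial genes of several kinds were lower with tumors. Of 15 goblet cell genes 8 fell (13 adjusted over the list alone; median -1.82, camera adjusted p = 3.12e-10), among them Muc2 (-2.45 ± 0.45, SE, 3 against 3 arrays, adjusted p = 0.0323), the goblet cell transcription factor genes Spdef (-2.39 ± 0.40) and Atoh1 (-1.73 ± 0.36), and Ang4 (-2.98 ± 0.22, adjusted p = 0.00265). Of 18 enteroendocrine genes 4 fell and Tac1, which neurons also express, rose (8 and 1 adjusted over the list alone; median -0.89, adjusted p = 0.000599). Chga, of hormone granules, had -1.87 ± 0.35, and the serotonin synthesis gene Tph1 had -1.51 ± 0.26. Of 33 genes of xenobiotic metabolism 5 fell (8 adjusted over the list alone; median -0.67, adjusted p = 3.46e-07), such as the sulfotransferase gene Sult1a1 (-1.97 ± 0.28) and Aldh1b1 (-1.64 ± 0.28). Of 8 genes of short-chain fatty acid transport and sensing 2 fell (4 adjusted over the list alone; median -0.74, adjusted p = 0.00267), the receptor gene Ffar2 (-1.85 ± 0.31, adjusted p = 0.0291) and the transporter partner gene Bsg (-1.15 ± 0.25). These 4 lists had adjusted p = 0.288 with an estimated correlation.

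Gene lists of fuel use were called lower in the same arrays. Few of their members passed, in a comparison where 5.70% of all features did. Of 18 PPAR target and ketogenesis genes 2 fell, among them the fatty acid binding protein gene Fabp2 at -1.49 ± 0.29 (list adjusted p = 0.00141, and adjusted p = 0.515 with an estimated correlation). Acads, which oxidises butyrate and other short fatty acids, had -1.52 ± 0.19 (adjusted p = 0.018) and was the 1 member of 23 beta-oxidation genes to fall (adjusted p = 0.00141, and adjusted p = 0.515 with an estimated correlation). Oxidative phosphorylation genes fell in 2 of 34 cases (11 adjusted over the list alone; median -0.44, adjusted p = 2.34e-09, and adjusted p = 0.288 with an estimated correlation). Of 17 tight junction genes Cldn15 (-1.90 ± 0.26) fell (5 adjusted over the list alone; adjusted p = 0.00021), and of 10 adipocyte genes 4 fell (8 adjusted over the list alone; median -2.80, adjusted p = 1.09e-05), led by Adipoq (-5.57 ± 1.15); both had adjusted p = 0.515 with an estimated correlation. Smooth muscle genes (median 1.06, adjusted p = 0.00141), enteric neuron and glia genes (adjusted p = 0.00114) and genes of T and natural killer cells (median 1.49 over 18, adjusted p = 0.00267) were called higher as lists, each with adjusted p = 0.534 with an estimated correlation, and Pgm5 (1.63 ± 0.38) was the member that passed. The value of T and natural killer cells rested on array 1 with tumors (3.00 above the DMH mean, against 0.169 and 1.19 in arrays 2 and 3), and the median was 0.67 without it.

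Calls that depended on scaling, all lower, were ribosomal proteins (5 of 37 fell; adjusted p = 1.57e-07, and 1.24e-11 to 0.889 over 16 alternatives), surface colonocytes (3 of 21 fell, among them Car1 at -1.90 ± 0.40; 0.00141, and 0.000685 to 0.123) and endoplasmic reticulum stress (Calr of 21 fell; 0.00326, and 0.00127 to 0.0716). Each had its 2 highest values with quantile scaling and normexp. NRF2 response genes (0.00819, and 0.00127 to 0.381; Tkt fell by 0.99, but another probe of it had the opposite sign), p53 targets (0.0294, and 0.0156 to 0.179, although Pmaip1 rose by 0.61) and heat shock genes (0.0294, and 0.0111 to 0.265) lost their calls with quantile scaling too. MHC class II genes were called higher (median 0.96 over 10; adjusted p = 0.0115, and 0.000355 to 0.163), with the highest value, and a median of 0.41, without array 1 with tumors. Without that array p53 targets had 0.179, without array 2 with tumors heat shock had 0.0825, and without array 3 with tumors heat shock had 0.0637 and NRF2 0.0636. With an estimated correlation every list in this paragraph had an adjusted p of at least 0.288 with an estimated correlation. Clock genes were not called as a list (adjusted p = 0.0789), yet 5 of 17 rose and 2 fell, with Dbp at 1.66 ± 0.29 and Npas2 at -1.54 ± 0.19.

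The largest rises with tumors were in Ciart (log2 3.59 ± 0.76), a clock repressor gene, Ccdc182 (at least 3.62-fold), Adh4 (3.28 ± 0.72), Zfp979 (3.24 ± 0.69), Gucy1b2 (3.19 ± 0.48), Fat2 (at least 3.25-fold), Olfr380, Brinp3, Atp6v1b1 and Sphkap. Falls were largest in Adipoq, Mitf (at least 10.1-fold lower), Srrm3 (-4.47 ± 0.44), Car3 (-4.42 ± 0.90), Cacna1f (at least 5.42-fold lower), Mrap (at least 8.84-fold lower), Ugt2b5 (-3.75 ± 0.57), Retn (-3.72 ± 0.76), Ugt2b38 (-3.69 ± 0.62) and Thrsp (-3.65 ± 0.62). Of 3 arrays with tumors 2 were well above background for Adipoq, Retn and Hcar2 and 1 for Ugt2b38, and of 3 DMH arrays 2 for Ciart and 1 for Adh4. Adipoq and Retn encode fat cell hormones, and the Ugt2b genes form a family of similar sequence. Values that did not pass were Slc5a8 -0.98 (adjusted p = 0.111), Hcar2 -1.30 (0.108), Cdkn1a -0.51 (0.104), Slc16a1 -0.14 (0.574), Myc -0.21 (0.524), Mki67 -0.38 (0.281) and Cyp2e1, at least 5.48-fold lower (0.0538).

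With tumors, limma called 1252 features (756 higher and 496 lower; 752 named genes) of 6573 with an unadjusted p under 0.05. The balance turned to 435 higher and 484 lower after quantile scaling. In the authors' values, where the median of all genes was -0.109 against 0.0841 here, 414 were higher and 1542 lower. In 42.6% of features the groups did not overlap, where chance gives 10%. The count was 317 without array 2 and 443 without array 3 without tumors, 53 without array 3 with tumors, 487, 4 and 4 without DMH arrays 1, 2 and 3, and 356 in a fit of only these 6 arrays. It was 35 with no scaling, 190 with no filter on dim probes, 5245 with array weights, and 4 each with slide as a random block and with DMH arrays 2 and 3 averaged. With all 3 DMH arrays averaged limma called 0 (1997 at an unadjusted p under 0.05). Of 64 called genes named by rule, Ang4 and Mitf stayed called whichever array was left out.

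Butyrate arrays without tumors (3) against those with tumors (3) ask what differs between treated animals by tumor status, and test directly whether the 2 groups' changes from DMH differ. Genes of fuel use and detoxification were higher without tumors. Of 23 beta-oxidation genes 14 rose (16 adjusted over the list alone; median 0.72, camera adjusted p = 3.44e-07, and adjusted p = 0.431 with an estimated correlation), such as Hadh (1.35 ± 0.22, SE, 3 against 3 arrays, adjusted p = 0.0144) and Cpt1a, which admits fatty acids to mitochondria (1.23 ± 0.21). Of 18 PPAR target and ketogenesis genes 6 rose (8 adjusted over the list alone; median 0.82, and 0.44 without array 1 without tumors; adjusted p = 0.000543, and adjusted p = 0.528 with an estimated correlation). Of 33 genes of xenobiotic metabolism 11 rose (18 adjusted over the list alone; median 1.06, adjusted p = 1.86e-06, and adjusted p = 0.365 with an estimated correlation), with Sult1a1 at 1.88 ± 0.28 and the cytochrome gene Cyp2c55 at 2.77 ± 0.44. Of 17 clock genes 6 rose (7 adjusted over the list alone; median 0.50, adjusted p = 0.00248, and adjusted p = 0.365 with an estimated correlation), with Cry2 at 0.88 ± 0.15.

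Inflammatory and immune genes were lower without tumors than with them. Of 33 genes of NF-kB and inflammatory cytokines 8 fell (13 adjusted over the list alone; median -0.90, adjusted p = 3.60e-05, and adjusted p = 0.365 with an estimated correlation), with the adhesion gene Icam1 at -1.77 ± 0.34, Il1b at -1.73 ± 0.34 and Cxcl5 at -5.05 ± 0.90, with 1 of 3 arrays without tumors well above background for Cxcl5. Of 15 genes of macrophages and dendritic cells 4 fell (9 adjusted over the list alone; median -0.86, adjusted p = 0.000379, and adjusted p = 0.365 with an estimated correlation), with Aif1 at -1.53 ± 0.32. Genes of B and plasma cells had a median of -1.39 over 15 (4 lower adjusted over the list alone; adjusted p = 0.00291, and adjusted p = 0.528 with an estimated correlation). That value rested on array 1 with tumors (2.56 above the DMH mean, against 0.246 and 0.963 in arrays 2 and 3) and was -0.66 without it. Neutrophil genes fell in 4 of 7 cases (median -1.64, adjusted p = 0.00248, and adjusted p = 0.492 with an estimated correlation), with S100a8 at least 14.3-fold lower, but the list had adjusted p = 0.114 with slide as a fixed block (0.000649 to 0.114 over 16 alternatives). That block fit sets array 1 with tumors alone against the arrays without tumors, which share its slide. With members not well above background at their bound the medians of the NF-kB and neutrophil lists were -0.70 and -1.34. Ribosomal protein genes fell in 19 of 37 cases (23 adjusted over the list alone; median -0.70, adjusted p = 5.95e-11, and adjusted p = 0.224 with an estimated correlation), with Rpl11 at -1.65 ± 0.14 and Rpl6 at -1.93 ± 0.18.

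Several other calls depended on array 1 with tumors, the array on the slide of the group without tumors. With slide as a fixed block, it alone stands for the group with tumors. Higher without tumors were tight junctions (5 of 17 rose, such as Cldn15 at 1.40 ± 0.26; adjusted p = 0.00285, and 7.42e-07 to 0.148 over 17 alternatives), surface colonocytes (4 of 21 rose, such as Car1 at 2.00 ± 0.40, and Ceacam1 and Lypd8 fell; 0.011, and 0.00291 to 0.0839) and enteroendocrine cells (3 of 18 rose, such as Chga at 1.70 ± 0.35; 0.00812, and 0.000864 to 0.102). Lower were MHC class II (2 of 10 fell; 0.00677, and 2.40e-06 to 0.118) and T and natural killer cells (2 of 18 fell, such as Cd4, at least 1.52-fold lower; 0.00248, and 2.28e-09 to 0.179). Each of these 5 had its highest value without that array. DNA repair (Alkbh3 fell, though another probe of it had the opposite sign; 0.00677, and 0.000444 to 0.0596) and proliferation (Mcm2 of 38 fell; 0.00677, and 2.45e-05 to 0.213) had 0.0556 and 0.148 without it. With slide as a fixed block Wnt targets (Lef1 at -2.02 ± 0.31 and Tcf7 at -2.14 ± 0.37; 0.00677, and 0.000177 to 0.66) turned direction with adjusted p = 0.66, and adipocytes (median 1.79, and 0.93 without array 1 without tumors; Adipoq at 4.15 ± 1.15; 0.00248, and 0.000236 to 0.145) had 0.145. Endothelium was called higher (3 of 14 rose and Prox1 fell; 0.017, and 0.00275 to 0.119), with a median of 0.42, and had 0.119, with a median of 0.20, without array 1 without tumors. The endothelium call was also lost with slide as a fixed block. Mast cells (Fcer1a fell; 0.0352, and 0.0106 to 0.954) and squamous epithelium (3 of 10 fell, Ly6d at -3.68 ± 0.35; 0.0439, and 0.0185 to 0.404) were called lower but reached 0.954 and 0.404 with slide as a fixed block. Without array 1 without tumors DNA repair had 0.0596, proliferation 0.213, mast cells 0.197 and squamous epithelium 0.0596. Without array 3 with tumors Wnt targets had 0.0629, mast cells 0.115 and squamous epithelium 0.108. Mast cells had 0.0834 without array 2 with tumors, squamous epithelium 0.0858 without array 3 without tumors and 0.0613 without DMH array 1, and endothelium 0.075 without array 1 with tumors. Every list in this paragraph had an adjusted p of at least 0.365 with an estimated correlation. Goblet cells (adjusted p = 0.073), smooth muscle (0.401) and enteric neurons and glia (0.731) were not called.

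**Figure D3:**
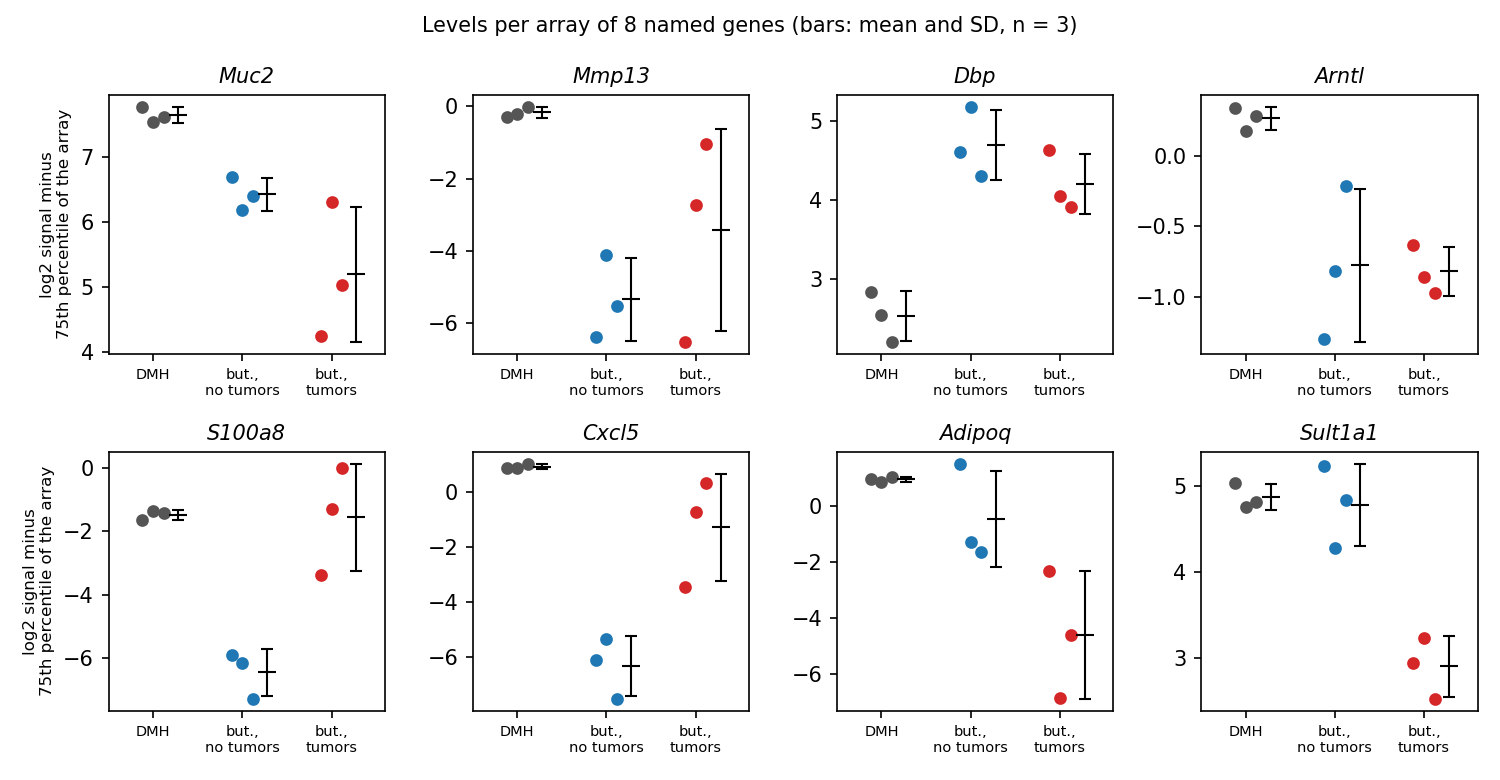
Log2 signal minus the array's 75th percentile for 8 genes, with 1 point per array and the mean and SD (n = 3) of each group. Sult1a1 is lowest with tumors, S100a8 and Cxcl5 are lowest without tumors, and Dbp and Arntl differ from DMH in opposite directions.

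Ffar2 (1.21 ± 0.31, adjusted p = 0.0413), Bsg (0.92 ± 0.25) and Cdkn1a (0.73 ± 0.18, adjusted p = 0.0361) were higher without tumors. The 10 largest rises were in Adipoq, Apol10a (3.16 ± 0.70), Ugt2b36 (3.12 ± 0.58), Ugt2b38, Adam18 (3.01 ± 0.44), Olfr1156, Cyp2c55, Ces1g (2.75 ± 0.70), Cyp2c66 and Olfr312. The 10 largest falls were in Defa23 (-5.54 ± 1.21), Cxcl5, S100a8, Clca4b (-4.59 ± 0.93), Arid3a (at least 5.2-fold lower), Defa20, Trim59 (-4.23 ± 0.92, and -1.68 in a dimmer probe), Defa22, Pik3cd (at least 9.84-fold lower) and Ly6d (-3.68 ± 0.35, adjusted p = 0.00918). Defa20, Defa22, Defa23, Clca4b and Arid3a were lower in array 1 with tumors, on the slide of the arrays without tumors, than in arrays 2 and 3 with tumors. Without tumors 1 of 3 arrays was well above background for Defa23 and Hcar2 and 2 of 3 for Trim59, and with tumors 2 of 3 were for Adipoq, Ugt2b36 and Hcar2 and 1 of 3 for Ugt2b38. The Cyp2c and Ces1 genes, like the defensin and Ugt2b genes, belong to families in which a probe can read several members. Values that did not pass were Muc2 1.23 (adjusted p = 0.0948), Slc5a8 1.00 (0.0874), Slc16a1 0.52 (0.0585), Hcar2 -1.44 (0.0687), Myc -0.51 (0.129) and Mki67 -0.21 (0.53).

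Between the butyrate groups, limma called 2976 features (1440 higher and 1536 lower; 1913 named genes) of 7599 with an unadjusted p under 0.05, and 33.4% of features did not overlap, where chance gives 10%. The balance turned to 1457 higher and 924 lower with quantile scaling, and was 3749 higher and 633 lower in the authors' values, where the median of all genes was 0.359. With slide as a fixed block 2462 were called (999 higher and 1463 lower), of which 940 were among the 2976. Slide 1 alone holds both groups, so that block fit sets array 1 with tumors against the 3 arrays without tumors. In a limma fit of only these 6 arrays 0 were called, with 5838 at an unadjusted p under 0.05, so the 2976 calls rest on a spread shared with the DMH arrays. The count was 1069, 1071 and 1287 without arrays 1, 2 and 3 without tumors, 7774 without array 1 and 177 without array 3 with tumors, and 1793, 1008 and 1033 without DMH arrays 1, 2 and 3. It was 1 with no scaling, 1442 with no filter on dim probes, 7454 with array weights and 1145 with DMH arrays 2 and 3 averaged. Of 111 called genes named by rule, 7 stayed called whichever array was left out: Fcer1a, Il1a, Ly6d, Rpl11, Rpl23, Rpl6 and S100a8.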

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

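The tests on a shift shared by slide 1, on the muscle wall, on scan day and on the clock genes were chosen only after the results were seen; the counts of other splits and the test on low signal were chosen before.

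The 2976 features called between the butyrate groups stand here because the groups' changes from DMH differed when the difference itself was tested. Of the 10 splits of these 6 arrays, the highest other called 1 feature and the real one 2976, the 1 split with as many, and 10 splits are too few for a share under 0.05. Because array 1 with tumors lies on slide 1 with the arrays without tumors, a shift shared by the arrays of slide 1 may account for part of the difference. On an axis from 0 (arrays 2 and 3 with tumors) to 1 (arrays without tumors) that array sat at 0.616, against 0.894 to 1.141 for the others of the slide, between the values that a shared shift and a group difference alone would need, so both stay open. The low signal of the slide 1 arrays would concentrate calls among the dimmest features. The brightest and the dimmest features were called at nearly the same rate (14.8% and 15.1%, ratio 0.98). That argues against low signal as the main cause, although the ratio fell just short of the bound set beforehand for excluding it. A biological difference by tumor status stays among the open explanations, with its sign tied to the label that was followed.

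Differences of single genes were tested in the same way, without tumors minus with tumors. Higher were Adipoq (4.15), Apol10a (3.16), Ugt2b36 (3.12), Ugt2b38 (3.10), Adam18 (3.01), Olfr1156 (2.93), Cyp2c55 (2.77), Ces1g (2.75), Cyp2c66 (2.70) and Olfr312 (2.59). Lower were Defa23 (-5.54), Cxcl5 (-5.05), S100a8 (-4.87), Clca4b (-4.59), Arid3a (-4.59), Defa20 (-4.28), Trim59 (-4.23), Defa22 (-4.09), Pik3cd (-4.08) and Ly6d (-3.68). The values of S100a8, Arid3a, Defa22 and Pik3cd are fitted, with a group not well above background, and are no bounds. Some of these differences went in part with slide 1. In array 1 with tumors Defa20 had a level of -0.09, against 3.07 and 3.80 in arrays 2 and 3 with tumors and -4.13 to -0.91 without tumors. Defa22, Defa23, Clca4b and Arid3a in that array also lay between the 2 sets. Ly6d (4.34 against 2.92 and 3.31) and Adam18 (-4.19 against -4.07 and -4.20) did not.

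Smooth muscle and enteric neuron genes were higher and goblet cell genes lower in the butyrate arrays. A lower share of epithelium would raise all other cell types alike. The smooth muscle median lay above the fibroblast and endothelium medians in 6 of 6 butyrate arrays, by 1.06 on average (SD 0.394). So these lists did not rise alike. They were set against each other after their medians had been seen, so the gap is no independent test of a lower share of epithelium. More muscle wall in the butyrate samples stays open: smooth muscle and enteric neuron medians went together with r = 0.6 over 6 arrays (exact permutation p = 0.221; rho = 0.429, exact permutation p = 0.419; r = 0.687 without the 2 arrays farthest from the median), 1 relation tested. Scan day and treatment cannot be told apart, since 0 scan days hold both butyrate and DMH arrays. An effect of butyrate itself was not separated from these.

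Clock genes differed in opposite directions with butyrate, and a candidate explanation is the time of day at which the mice were killed. In the comparison of all butyrate arrays with DMH, 9 genes of the Dbp, Tef, Hlf, Per, Nr1d and Ciart arm had a median log2 change of 1.50 and Arntl, Clock and Npas2 of -1.07, a gap of 2.57. These genes were grouped after their directions had been seen, so the gap restates the pattern and does not support that explanation, which stays open. A constant per array shifts both arms alike and cannot change this gap. Quantile scaling and normexp, which could change it, left gaps of 2.50 and 1.60, so scaling between arrays is excluded as its whole cause. Killing times are not in the labels used here, and an effect of butyrate on the clock stays open.

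For butyrate against DMH the real split called 2020 features, and 2 of 84 splits, itself included, called as many, a share under 0.05. The splits treat the 9 arrays as exchangeable and independent, so they exclude only a random division of such arrays. They do not exclude slide or scan day, which follow the treatment, nor a dependence between DMH arrays 2 and 3. With these 2 averaged 4 features were called. The other such split, with 3749, parts the arrays without tumors from the other 6, and so follows slide 1 and the tumor status, a structure of the samples. A split of arrays 1 and 2 without tumors and array 1 with tumors, all on slide 1, from the other 6 called 1095. Without the arrays of slide 1 the count was 2505. For the arrays without tumors against DMH (real 6695, highest other 0 in limma) and with tumors against DMH (real 1252, highest other 0), the real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05.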

How the results depend on the processing

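Of the alternatives, slide as a random block, averages of DMH arrays and the fit without slide 1 were chosen only after the results were seen. Counts are given in the order butyrate against DMH, without tumors against DMH, with tumors against DMH, and without against with tumors, where the reported counts were 2020, 6695, 1252 and 2976. With the 3 DMH arrays averaged into 1 sample limma called 0, 0, 0 and 0 (1524, 4278, 1997 and 5838 at an unadjusted p under 0.05), with the lone sample assumed to vary like the other groups, and with DMH arrays 2 and 3 averaged 4, 2909, 4 and 1145. Leaving out 1 array gave 7 to 3626, 2841 to 9941, 4 to 1792 and 177 to 7774. Slide as a random block gave 17, 1010, 4 and 2242. Signal over background limits what dim probes show: with no filter on them 511, 4908, 190 and 1442 were called. With no scaling 35, 1550, 35 and 1 were called, with median log2 changes of all genes of -0.763, -1.004, -0.526 and -0.481, and 0, 5, 1 and 0 of the calls higher. The authors' values gave 1197, 5628, 1956 and 4382, of which 469, 3777, 414 and 3749 were higher, with medians of 0.254, -0.109 and 0.359 in the last 3. Without the filter the medians were 0.15, 0.219 and -0.142 in the first, the third and the last. Calls with quantile scaling were higher in 435 and lower in 484 with tumors against DMH and higher in 1457 and lower in 924 between the butyrate groups. Normexp gave 857 higher and 895 lower, 465 and 668 with tumors, and 1760 and 1009 between the butyrate groups. Array weights gave 12107, 12768, 5245 and 7454; an added 2-fold minimum 1338, 3924, 866 and 1750; a threshold of 0.1 gave 4543, 9313, 3806 and 5694. A fit with 3 groups gave 5051 for butyrate against DMH, and fits of only the 6 arrays compared gave 9697, 356 and 0 for the others (limma; 5838 at an unadjusted p under 0.05 for the last). With fewer arrays the fit has fewer degrees of freedom; the cause of the other shifts was not tested.

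No clear pairing by replicate number was seen: 4 of 9 same-numbered pairs had a correlation over 0.1, and 4 of 9 arrays correlated best with their own number. These correlations ran from -0.01 to 0.264, and so few arrays per group cannot exclude a pairing. With the replicate block 583, 6866, 477 and 2809 were called.

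Of gene lists, 17, 17, 19 and 21 were called, and leaving out 1 array gave 14 to 21, 14 to 17, 19 to 21 and 14 to 26. Camera with an estimated correlation called 0, 0, 0 and 0 (1, 4, 7 and 5 at an unadjusted p under 0.05) and fry 3, 16, 9 and 12. Quantile scaling and normexp each gave 11 for butyrate against DMH. In the 17, 16, 16 and 17 alternatives other than these tests, 5, 10, 12 and 8 lists were called each time.

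Named genes turned sign in 28 cases, each against DMH. Without tumors and with no scaling these were Txnip (-0.00158), Acadsb (-0.46), Hadh (-0.14), Acat1 (-0.40), Cpt1a (-0.28), Hmgcs1 (-0.23), Msmo1 (-0.15), Dhcr7 (-0.46), Srebf2 (-0.22), Sc5d (-0.14), Sqle (-0.18), Cyp51 (-0.14), Perp (-0.41), Bcl2l1 (-0.44), Gbp2 (-0.062), Ctss (-0.40), Tjp1 (-0.11), Dnajb1 (-0.55), Canx (-0.34), Ddit3 (-0.23), Tac1 (-0.26), Vwf (-0.36) and Emcn (-0.22), all smaller than the shift of the median of all genes (-1.004). With tumors and no scaling it was Pmaip1 (-0.00233). With the mean of all probes of a gene they were Cyp51 (-0.057), Mdm2 (0.082), Canx (-0.94) and Ceacam1 (0.12), genes whose probes disagree. Canx passed in that direction (limma adjusted p = 0.0423). Without tumors against DMH, 49 of 171 called genes named by rule had another probe. For 13 of them such a probe had the opposite sign, and for 3 it was called in the opposite direction. In the other comparisons, in the order above, 2, 2 and 4 genes had a probe of opposite sign, with 0 called. No other called gene named by rule turned sign under an alternative. There were 2153, 3675, 2048 and 2709 values on the same side of the threshold, and 792, 1035, 749 and 1127 that no longer passed. Scan day as a block was not run, as no day holds both treatments, and slide as a fixed block was run between the butyrate groups alone. There only array 1 with tumors shares a slide with the arrays without tumors.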

Other observations

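No test in this part was chosen after the result was seen; all values come from lists and genes fixed beforehand.

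Several gene lists were called in none of the 4 comparisons (camera), and members that passed are given as values. Cholesterol synthesis genes had 7 of 24 members higher without tumors than in DMH, each by less than the shift of the median of all genes with no scaling, -1.004 (adjusted p of the list 0.681). Of these members, Cyp51, Dhcr7 and Hmgcs1 had another probe of the opposite sign. Genes that respond to histone deacetylase inhibitors, a class that includes butyrate, had a median of -0.23 over 15 members for butyrate against DMH (adjusted p = 0.156). Interferon-stimulated genes (median 0.05 over 28; adjusted p = 0.873), apoptosis genes (0.11 over 30; 0.737) and immediate early genes (0.22 over 19; 0.87) lay near the median of all genes, 0.08, and Fosb of the last list rose by 1.28 ± 0.22. For interferon-stimulated genes the test pointed down while the median was above 0.

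Markers of other tissue parts in the same comparison were fibroblasts and matrix (median 0.11 over 18; adjusted p = 0.873), tuft cells (0.03 over 10, with a mean of -0.03; 0.931), small intestine and Paneth cells (0.26 over 12, with the test pointing down; 0.926), posterior Hox genes (-0.38 over 7; 0.487) and skeletal muscle (0.14 over 9; 0.625). Of the skeletal muscle genes 2 passed, the myosin genes Myh1 (1.36) and Myh2 (1.90). The list of B and plasma cells was not called for butyrate against DMH (median 0.64 over 15, with the test pointing down; adjusted p = 0.931). Array 1 with tumors had 2.56 and the other 5 from -0.836 to 0.963 relative to the DMH mean. Of its members the antibody joining chain gene Jchain (-2.25 ± 0.55) and the plasma cell receptor gene Tnfrsf17 (-1.58 ± 0.38) fell.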
